A study of Homo sapiens with 2 samples.

How the data were processed

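RNA-seq libraries of LNCaP cells were compared between 2 groups of 1 library each, taken from the sample titles: cells exposed to the CM of M2 macrophages labelled nc-YY1, and of M2 macrophages labelled oe-YY1. The labels do not spell out nc, oe or CM. The treatment label of each library also carries the word cocultured, which alone does not say whether macrophages were present with the LNCaP cells. Per the labels' protocols, 2 ug of total RNA entered each library, and the kits named include poly(A) selection, ribosomal RNA depletion and a stranded library preparation, with no statement of which step was used for which library. The labels also carry an adipogenic treatment protocol and a day 0 time, which were not used.

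Expression values were deposited as FPKM (fragments per unit of transcript length and of library size), per the file headers, and were made with StringTie 2.1.0, per the submitters' processing notes. The aligner is not given in the sources used here. The processing notes name the mouse build mm10, but the gene identifiers and coordinates are human. Of 12075 identifiers, 11946 carry the suffix used when GENCODE annotation is mapped to GRCh37, and 97 of 11995 identifiers matched in GENCODE 29 had the same start and end there. Coordinates are therefore printed as the deposited table gives them, and GRCh37 is an inference from the identifiers. The table held protein-coding genes alone, and every gene had at least 0.50 FPKM in the higher library, which was checked on the values. The authors' tables of changed genes gave log2 fold changes, fold changes and p-values and q-values, per the file headers. Their fold changes were linear ratios of oe over nc on the scale of FPKM + 1, and not plain ratios of FPKM. The largest was 637, for a log2 fold change of 9.32. The authors' columns headed FPKM with a group prefix held log2(FPKM + 1), and their log2 fold change was the difference of these, which was checked on the values. The authors' p-values and q-values were 1 for every gene and were not used. The authors' tables held the genes with a fold of at least 1.5.

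The number of reads per library is unknown, since FPKM holds no counts. Among 141 genes with low values in both libraries, 138 distinct ratios were found to 3 decimals, so no common step that would give the relative depth was seen. FPKM of the listed genes summed to 216207 in the nc library and 198520 in the oe library. The mitochondrially encoded genes held 12.2% and 12.4% of these sums, and the 20 most abundant genes 14.8% and 15.5%. Of the listed genes, 41 were at 0 in the nc library and 16 in the oe library, and for these no fold is given. No interval can be given for a single FPKM value.

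The log2 ratio of a gene is log2(FPKM + 1) in the oe library minus that in the nc library, a scale that understates differences of low genes. A pseudocount of 1 was used, and genes needed at least 1 FPKM in the higher library (11126 genes). A gene was counted as higher or lower at a difference of 2-fold. With 1 library per group no test across samples could be made. For each of 27 gene lists fixed before the data were examined, the median log2 ratio of measured members was set against 10000 random lists of the same size, drawn from genes outside the list in 20 bins of mean expression. A list was said to stand apart at a percentile under 2.5 or over 97.5, which describes these 2 libraries and is not a test of the conditions. 1 list, the endothelial markers, had no measured member, which left 26. Lists share members. The same was done for 138 families of at least 10 genes that share the letters of their symbols.

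Named genes followed a rule fixed before the data were examined: YY1, IL6, IL6R, IL6ST, STAT3, SOCS3 and KLK3, with others not reported here; the 12 highest and 12 lowest log2 ratios among genes of at least 5 FPKM in the higher library; and at most 4 members with the largest log2 ratio past 2-fold in each list, or the most abundant member of a list with none. USP18, ISG15, IFI6, STEAP2, ASPM, CCNE1, CCNE2, LCP1, CD68, CTSS and AP3S2 fall outside that rule and were chosen after their values were seen. Removal of a repeated symbol from the lists was also decided after the data were examined, and it changed the histone list alone. IL6 was not analysed here.

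On simulated data with the genes and expression of this comparison (11126 genes), random lists of 25 genes were called higher in 2.0% and lower in 4.5% of 200 draws with no shift. A shift of 0.25 on the log2 scale was called in 38.0% of draws, one of 0.5 in 97.0% and one of 1 in 100.0%. For these draws the log2 ratios were shuffled among genes of like expression and given random signs. Genes were thus independent and without a length trend, so these percents do not describe lists of genes that vary together. The 2-fold size rule recovered 1.0% of 200 genes with a simulated fold of 1.5, 22.0% at 2-fold, 85.0% at 3-fold and 94.5% at 4-fold. The noise in this size-rule simulation was assumed and was the same for every gene. It was smaller than the SD of 0.78 of the log2 ratios here, so these percents do not describe the noise of the 2 libraries.

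Alternatives fixed before the data were examined were pseudocounts of 0.1, 0.5 and 5; no filter, at least 5 FPKM in the higher library and at least 1 FPKM in both; centring on the median, the same 75th percentile and trimmed mean of log ratios scaling; thresholds of 1.5-fold and 4-fold; unmatched random lists; and the mean of the members. Scaling to the same sum, removal of the length trend, removal of genes that overlap another listed gene on the same strand, and matching on transcript length or GC content were chosen after the data were examined. Transcript length and GC content were taken from the longest protein-coding transcript in GENCODE 29, by gene identifier, for 11010 of the measured genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.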

Results

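Gene expression was measured by RNA-seq in LNCaP, an androgen-sensitive human prostate cancer cell line established from a lymph node metastasis, in 2 libraries. In the nc library the cells had been exposed to the CM of M2 macrophages labelled nc-YY1, and in the oe library to that of M2 macrophages labelled oe-YY1. Both treatment labels add the word cocultured. Macrophages of the M2 type are the polarisation state often compared with tumor-associated macrophages, and YY1 is a zinc finger transcription factor. The series asks how YY1 in such macrophages affects prostate cancer cells, with IL-6 named as a link. There was 1 library per group, so no difference below has a replicate check and none has a p-value. The deposited table listed 12075 protein-coding genes in FPKM, with a median of 5.39 in the nc library and 5.56 in the oe library. The number of reads behind these values is unknown. Log2 ratios and 2-fold differences are on the scale of FPKM + 1, which understates differences of low genes. Coordinates are as deposited, with the build GRCh37 inferred from the gene identifiers.

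Members of the list of IL-6, JAK and STAT3 targets and components were among the highest log2 ratios. SAA1, a serum amyloid A protein induced by inflammatory cytokines (ENSG00000173432.10_2, chromosome 11, 18287721 to 18291524), stood at 0.262 and 803 FPKM in the nc and oe libraries, a log2 ratio of 9.32, the highest of all genes that reached 5 FPKM. SAA2, its near-identical neighbour, was listed at 0 in the nc library and stood at 175 FPKM in the oe library, and reads of SAA1 and SAA2 may be divided between them. SERPINA3, a secreted protease inhibitor, stood at 0.754 and 223 FPKM, and LCN2, an iron-siderophore binding protein of innate defence, at 0.703 and 102 FPKM. Of 25 measured members of the IL-6, JAK and STAT3 list, 17 were at least 2-fold higher, 0 at least 2-fold lower and 8 differed by less than 2-fold. The median log2 ratio of the list was 1.73, above all 10000 random lists matched on expression. SAA1, SAA2, SERPINA3 and LCN2 were under 1 FPKM in the nc library. They passed the filter through the oe library alone and could only be higher. The members that reached 1 FPKM in both libraries had log2 ratios from -0.82 to 2.81.

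The components of the IL-6 receptor pathway differed in size. IL6ST, the signalling subunit shared by the IL-6 cytokine family, stood at 4.45 and 24.96 FPKM in the nc and oe libraries (log2 ratio 2.25), while IL6R, the ligand-binding subunit, stood at 14.9 and 19.7 FPKM (0.38). STAT3, the transcription factor downstream of that receptor, stood at 16.9 and 58.5 FPKM (1.73). SOCS3, a feedback inhibitor induced by STAT3, was listed at 0 in the nc library and stood at 4.42 FPKM in the oe library. YY1 itself stood at 9.58 and 10.25 FPKM (0.09) in LNCaP, and since the labels attach YY1 to the macrophages, this level does not check the labels. IL6 was not analysed here.

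Antigen presentation genes were higher together. HLA-DRA, the alpha chain of the MHC class II molecule HLA-DR (ENSG00000204287.13_2, chromosome 6, 32407619 to 32412823), stood at 0.962 and 700.0 FPKM in the nc and oe libraries (log2 ratio 8.48). CD74, the class II invariant chain, stood at 0.0923 and 251 FPKM (7.85), and HLA-DRB1 at 0.0893 and 115.9 FPKM (6.75), a value uncertain for a gene with close copies. Of 17 measured genes of MHC class I and antigen processing, 13 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 1.78 and no random list as high. The immunoproteasome subunit PSMB9 stood at 0.699 and 11.9 FPKM, HLA-B at 18.5 and 133 FPKM, HLA-E at 11.8 and 84.0 FPKM and the peptide-trimming enzyme ERAP1 at 2.12 and 16.5 FPKM. HLA-DRA, HLA-DRB1 and CD74 are also markers of macrophages and other leukocytes, and of that list of 36 markers, 26 were not analysed here and 9 were measured, of which 8 were at least 2-fold higher (median log2 ratio 3.20, above all random lists). Only LCP1, at 89.9 and 114 FPKM, and S100A9 reached 1 FPKM in both libraries. The other measured markers passed the filter through the oe library alone, so the direction and percentile of this list were largely set by the filter. Among the listed markers outside MHC class II, S100A9, a calcium-binding protein of myeloid and inflamed epithelial cells, stood at 1.43 and 270.2 FPKM, while CD68 stood at 0.632 and 4.18 FPKM and CTSS at 0.0409 and 5.87 FPKM. Of 16 fibroblast markers 13 were not analysed here, and the 3 measured differed by less than 2-fold (median log2 ratio 0.23, COL6A1 at 36.3 and 42.8 FPKM), and of 12 endothelial markers 11 were not analysed here and 1 did not reach 1 FPKM.

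Interferon-induced genes were mostly higher in the oe library, with exceptions. Of 32 measured members, 17 were at least 2-fold higher, 1 at least 2-fold lower and 14 differed by less than 2-fold (median log2 ratio 1.05, above all random lists). The guanylate-binding proteins GBP2 and GBP1, GTPases of cell-autonomous defence, stood at 3.09 and 53.02 FPKM and at 1.51 and 22.1 FPKM. IFIT3 stood at 0.315 and 6.08 FPKM. USP18, a protease that removes ISG15 from proteins and limits interferon signalling, was the member at least 2-fold lower, at 7.36 and 3.13 FPKM. ISG15 itself, at 64.0 and 41.7 FPKM, and IFI6, at 14.4 and 8.86 FPKM, were lower by less than 2-fold. Members under 1 FPKM in the nc library, IFIT3 among them, passed the filter through the oe library alone and could only be higher. NF-kappaB targets were higher in 12 of 16 measured members, with 0 lower, and had a median log2 ratio of 2.04, above all random lists. BIRC3, an inhibitor of apoptosis, stood at 0.271 and 52.1 FPKM, the adhesion molecule ICAM1 at 0.889 and 57.6 FPKM, and TNFAIP3, a feedback inhibitor of NF-kappaB, at 0.621 and 21.4 FPKM. The chemokine CCL20 was listed at 0 in the nc library and stood at 15.0 FPKM in the oe library. The NF-kappaB targets named here were under 1 FPKM in the nc library. They passed the filter through the oe library alone and could only be higher. The members that reached 1 FPKM in both libraries had log2 ratios from 0.21 to 2.26. Of 7 measured immune checkpoint ligands and chemokines, 4 were at least 2-fold higher and 0 lower. These were the chemokine CXCL10 (0.152 and 5.10 FPKM), the macrophage growth factor CSF1 (0.129 and 4.75 FPKM), CD276 (3.47 and 12.9 FPKM) and LGALS9, listed at 0 in the nc library and at 1.27 FPKM in the oe library. The median log2 ratio of that list of 22 was 1.18 (14 were not analysed here), and over members that reached 5 FPKM in the higher library it was 0.065 and the list no longer stood apart (-0.13 over members that reached 1 FPKM in both).

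Other genes among the highest log2 ratios were named by the fixed rule. UBD, a ubiquitin-like modifier induced by inflammatory cytokines, stood at 0.0724 and 266 FPKM in the nc and oe libraries, CFB, complement factor B, at 0.0683 and 129.5 FPKM, and PIGR, the transporter of polymeric immunoglobulins across epithelia, at 0.102 and 87.3 FPKM. C8orf4 stood at 0.490 and 118 FPKM. SERPINA3, SAA2, UBD and CFB each overlap another listed gene on the same strand, so part of their reads may belong to it.

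**Figure D1:**
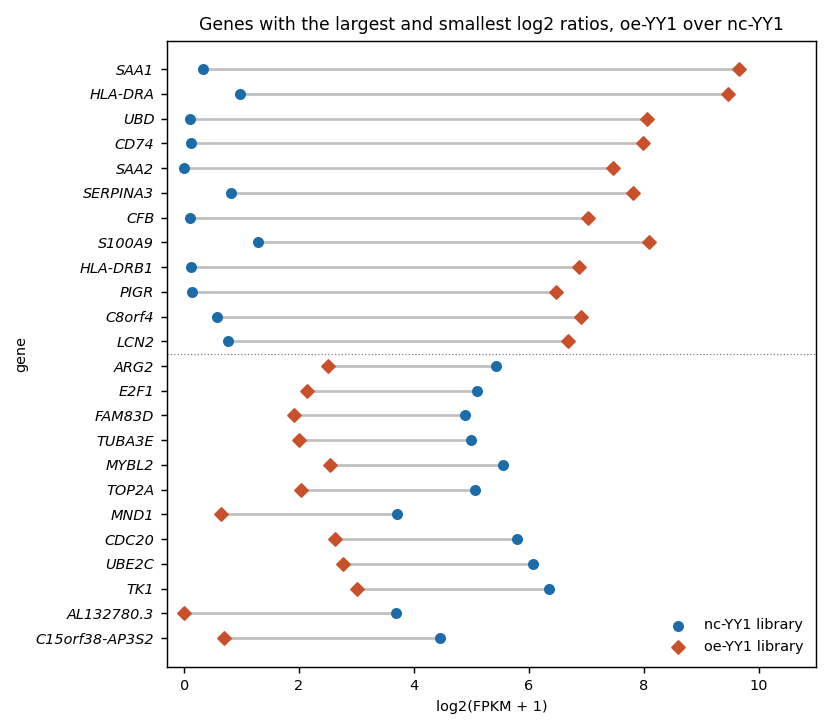
The 12 genes with the largest and the 12 with the smallest log2 ratio among genes that reached 5 FPKM, with log2(FPKM + 1) on the horizontal axis, circles for the nc library and diamonds for the oe library, 1 library each and no error bars. The upper genes lie near 0 in the nc library and up to 803 FPKM (SAA1) in the oe library, and the lower genes include TK1, at 80.8 and 7.04 FPKM in the nc and oe libraries.

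Cell cycle genes formed the most uniform group in the other direction. Of 51 measured members, 48 were at least 2-fold lower in the oe library and 0 at least 2-fold higher, with a median log2 ratio of -2.15, below all 10000 random lists. TK1, the thymidine kinase of S phase (ENSG00000167900.11_2, chromosome 17, 76170156 to 76183314), stood at 80.8 and 7.04 FPKM in the nc and oe libraries (log2 ratio -3.35), and UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, at 65.8 and 5.80 FPKM (-3.29). CDC20, the activator of that complex, stood at 54.5 and 5.19 FPKM (-3.16), and TOP2A, the DNA topoisomerase of dividing cells, at 32.4 and 3.11 FPKM (-3.02). The transcription factor E2F1, which drives genes of S phase, stood at 33.4 and 3.41 FPKM. Named by rule outside the list were MYBL2, a transcription factor of dividing cells (45.8 and 4.78 FPKM), MND1, a meiotic recombination protein (12.1 and 0.562 FPKM), FAM83D, a spindle protein (28.5 and 2.77 FPKM), and ARG2, mitochondrial arginase (42.0 and 4.66 FPKM). The members that differed by less than 2-fold were ASPM, at 1.52 and 0.369 FPKM, and the cyclins CCNE1, at 6.46 and 4.06 FPKM, and CCNE2, at 8.08 and 5.91 FPKM. The list of replication-dependent histones held 68 symbols, which include older and newer names of the same genes. Of these symbols 43 were not analysed here. Of the 22 measured histones 2 were at least 2-fold higher and 3 at least 2-fold lower, with a median log2 ratio of 0.01 at percentile 47.2. The larger HIST family by symbol (46 measured) stood apart in the higher direction, with a median of 0.25 at percentile 99.6. Of that family 6 genes were at least 2-fold higher and 3 at least 2-fold lower. HIST1H4C stood at 8.63 and 0.898 FPKM and HIST2H2BF at 3.88 and 12.1 FPKM, values uncertain for genes of near-identical copies whose mRNAs lack poly(A) tails.

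3 further genes among the lowest log2 ratios are uncertain. C15orf38-AP3S2, a read-through gene, stood at 20.8 and 0.622 FPKM while AP3S2, which it overlaps, stood at 4.04 and 10.5 FPKM, and AL132780.3, which overlaps HAUS4 and AJUBA, stood at 11.9 FPKM in the nc library and was listed at 0 in the oe library. TUBA3E, a tubulin with near-identical copies, stood at 30.9 and 2.98 FPKM.

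Androgen-induced genes were lower in the oe library. KLK3, which encodes prostate-specific antigen (ENSG00000142515.14_3, chromosome 19, 51358171 to 51364020), stood at 358 and 77.6 FPKM in the nc and oe libraries (log2 ratio -2.19). KLK2, a related kallikrein, stood at 93.4 and 12.7 FPKM, EAF2 at 37.8 and 5.22 FPKM and SLC45A3 at 68.0 and 12.1 FPKM. Of 38 measured members, 17 were at least 2-fold lower, 1 at least 2-fold higher and 20 differed by less than 2-fold, with a median log2 ratio of -0.85, below all random lists. STEAP2, a metalloreductase, was the higher member, at 3.39 and 17.9 FPKM. Of 7 measured androgen-repressed genes, 2 were at least 2-fold higher (among them TRIB1, at 5.10 and 14.9 FPKM) and 1 lower (DDC, at 10.7 and 1.20 FPKM). The median of that list was 0.89 at percentile 99.9, and it no longer stood apart with the mean of its members or under either stricter filter on low values.

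Of 20 measured immediate early genes, 9 were at least 2-fold higher and 0 lower (median log2 ratio 0.81, above all random lists). The call was lost at a median of 0.045 over members that reached 1 FPKM in both libraries, a filter that removes members near 0 in the nc library, and kept at 1.05 over members that reached 5 FPKM in the higher library. ATF3, a stress-induced transcription factor, stood at 31.5 FPKM in the oe library (log2 ratio 3.02), the mRNA-destabilising protein ZFP36 at 2.69 and 22.5 FPKM, KLF4 at 0.792 and 7.39 FPKM and JUNB at 46.5 and 219 FPKM. Of 10 measured ERK feedback genes, 3 were at least 2-fold higher and 1 lower (median 0.67, percentile 99.4), with SPRY4 at 0.113 and 6.13 FPKM and DUSP4, a phosphatase of ERK, at 6.98 and 0.950 FPKM. The higher members lay near 0 in the nc library, and over members that reached 5 FPKM the median was -0.28. The list did not stand apart without a filter on low values or with the mean of its members. Of 21 apoptosis regulators, 5 were at least 2-fold higher and 1 lower (median 0.61, above all random lists), among them BCL2L2 at 1.99 and 14.4 FPKM, a gene that overlaps a read-through gene, and BMF at 2.25 and 14.9 FPKM. BIRC5, also a mitotic gene, was the lower member, at 7.30 and 1.01 FPKM. Of 24 p53 targets, 3 were at least 2-fold higher and 0 lower (median 0.37, percentile 99.9). They were GDF15 at 60.0 and 192 FPKM, TP53INP1 at 30.4 and 76.5 FPKM and ZMAT3 at 1.96 and 5.98 FPKM. The list did not stand apart with the mean of its members. Of 29 genes of the unfolded protein and integrated stress response, 4 were at least 2-fold higher and 0 lower. They were ATF3, XBP1 at 31.9 and 161 FPKM, the cystine transporter SLC7A11 at 11.6 and 42.4 FPKM and DNAJB9 at 25.3 and 57.6 FPKM. The median of that list was 0.06 (percentile 99.0), against a middle 95% of -0.43 to 0.01 for matched random lists. It did not stand apart from lists drawn without matching.

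Of 23 epithelial genes, 3 were at least 2-fold higher and 1 lower (median log2 ratio 0.08, percentile 95.6). The laminin chain LAMB3 stood at 0.165 and 9.96 FPKM, the epithelial transcription factor ELF3 at 2.52 and 29.1 FPKM, the tight junction protein CLDN4 at 5.93 and 43.4 FPKM and keratin KRT19 at 9.62 and 2.15 FPKM. Of 41 mesenchymal and invasion genes 28 were not analysed here, and of the 11 measured 3 were at least 2-fold higher and 0 lower (median 0.40, percentile 97.9, a call lost under 5 of the alternatives tried besides the filter of 1 FPKM in both libraries). These were the matrix proteins FN1, at 37.98 and 288 FPKM, and THBS1, at 25.8 and 113 FPKM, and the protease MMP7, listed at 0 in the nc library and at 7.55 FPKM in the oe library. Of 27 neuroendocrine markers 20 were not analysed here, and of the 5 measured 1 was at least 2-fold lower, SYT4, at 33.2 and 6.77 FPKM, with a median of 0.01 at percentile 45.0.

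The metabolic and heat shock lists held few genes past 2-fold. Of 28 hypoxia and glycolysis genes, 3 were at least 2-fold higher, KDM3A at 1.27 and 5.33 FPKM, VEGFA at 8.17 and 24.4 FPKM and BNIP3L at 20.2 and 43.2 FPKM (median log2 ratio 0.11, percentile 96.6). Of 24 cholesterol synthesis genes, 3 were at least 2-fold lower (median -0.29, percentile 4.21). EBP, an isomerase of sterol synthesis, stood at 23.6 and 5.31 FPKM, while PMVK, at 70.1 and 33.1 FPKM, and TM7SF2, at 26.04 and 12.1 FPKM, fell short of 2-fold with the libraries set to the same 75th percentile. Of 20 fatty acid genes, FADS2 alone was at least 2-fold lower, at 26.5 and 11.2 FPKM (list median -0.33, percentile 6.81). The 15 heat shock genes all differed by less than 2-fold (median -0.21, percentile 60.0), with HSP90AB1 at 768 and 662 FPKM.

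The protein synthesis and respiration lists differed by less than 2-fold in every member. The 59 measured nuclear-encoded oxidative phosphorylation genes had a median log2 ratio of -0.58, below all random lists, with NDUFS5, a complex I subunit, at 529 and 350.4 FPKM. The 77 cytosolic ribosomal proteins had a median of -0.42 (percentile 0.70), with RPL41 at 943 and 757 FPKM, and the percentile was 8.33 among random lists matched also on transcript length. The 13 mitochondrially encoded genes had a median of -0.11 (percentile 94.1), with MT-ATP8 at 4145 and 3799 FPKM, and that median turned to 0.01 with the libraries scaled to the same sum. Short transcripts were lower in general: the 1101 genes with the shortest transcripts (median 1042 nt) had a median log2 ratio of -0.40, and the 1101 with the longest (median 9042 nt) a median of 0.24.

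**Figure D2:**
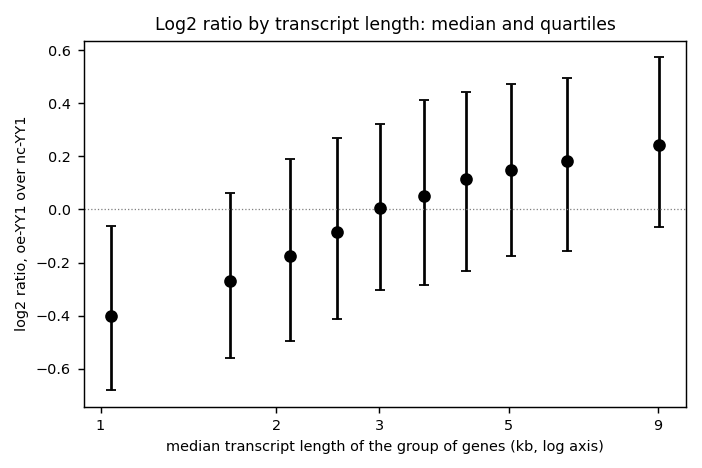
Median log2 ratio (oe over nc library, points) with quartiles (bars) in 10 groups of 1101 genes ordered by transcript length, plotted at each group's median length in kilobases on a log axis. The median goes from -0.40 in the group of shortest transcripts to 0.24 in that of the longest.

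Over all genes, 719 of the 11126 that reached 1 FPKM in the higher library were at least 2-fold higher in the oe library and 649 at least 2-fold lower, 12.3% in all. At 8-fold the counts were 59 higher and 9 lower, and at 16-fold 29 higher and 0 lower. Of 26 lists tested, 13 stood apart in the higher direction and 4 in the lower direction, where 1.3 would be set apart by chance if genes were independent. The authors' deposited tables listed 1776 genes as higher and 1735 as lower at a fold of at least 1.5, with p-values and q-values of 1 for every gene. These differences compare 2 libraries and not the conditions, and the counts depended on the pseudocount and on the filter on low values.

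**Figure D3:**
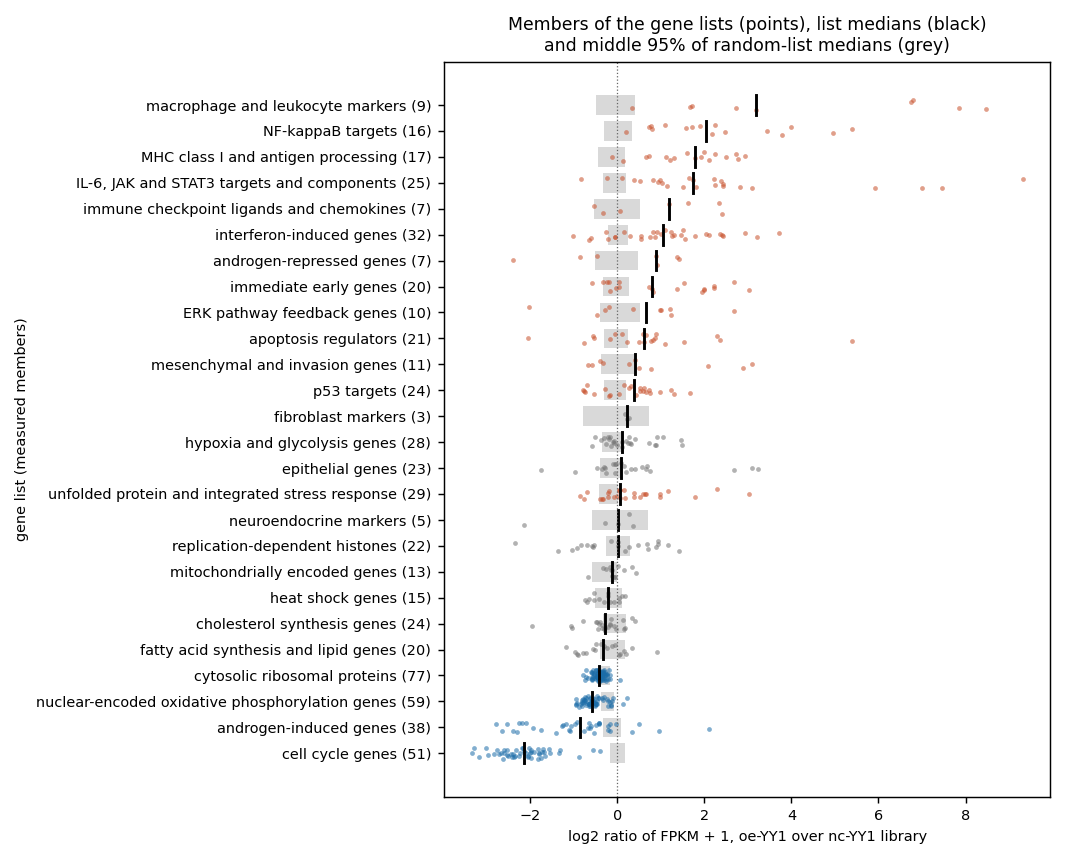
Log2 ratio (oe over nc library) of each measured member (points) of the 26 tested lists, with list medians (black lines) and the middle 95% of medians of matched random lists (grey bands), 1 library per group. Orange lists stood apart in the higher direction, blue lists in the lower direction and grey lists neither. The cell cycle list has the lowest median, -2.15, and the macrophage and leukocyte markers the highest, 3.20.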

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

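Scaling to the same sum, removal of the length trend or of overlapping genes, and matching on length or GC content were tests chosen only after the results were seen. Across 11 settings, 905 comparisons of the 88 named genes kept their side of 2-fold and direction, 24 fell below 2-fold and 0 reversed. Comparisons where a filter removed the gene are not counted. Most of these genes were named for large log2 ratios in the same 2 libraries. The log2 ratios of low genes, such as SOCS3 and CCL20, depended strongly on the pseudocount. They were much larger at a pseudocount of 0.1 and much smaller at 5. A pseudocount cannot change the sign of a ratio, however. The filters left each ratio unchanged, and scaling shifted the median of all genes little. That 0 reversed was therefore nearly fixed in advance. Of the list medians, 331 comparisons kept their call, 10 gained one, 17 lost one and 3 reversed. Calls gained were hypoxia genes at 0.15 (pseudocount of 0.1), 0.16 (5 FPKM) and 0.23 (mean); epithelial genes at 0.36 (mean) and 0.08 (GC-matched); cholesterol genes at -0.29 (unmatched) and -0.33 (mean); fatty acid genes at -0.33 (unmatched, and length-matched); and mitochondrially encoded genes at -0.11 (length-matched). The 2-fold counts moved past 1.5 times to 1124 higher (pseudocount of 0.1), to 289 higher and 272 lower (pseudocount of 5), to 458 higher against 524 lower (at least 1 FPKM in both libraries, where 7 lists stood apart higher), to 1700 and 1691 at 1.5-fold, and to 188 and 134 at 4-fold, also the numbers of genes in the authors' deposited tables at 4-fold. At 5 FPKM 508 were higher and 517 lower. The ERK feedback median turned to -0.28 at 5 FPKM and -0.23 at 1 FPKM in both, and lost its call at 0.10 (no filter) and 0.45 (mean). The checkpoint median turned to -0.13 at 1 FPKM in both and lost its call at 0.065 (5 FPKM). Other calls lost were the mesenchymal list at 0.47 and 0.44 (pseudocounts of 0.1 and 0.5), 0.28 (no filter, and 1 FPKM in both), 0.43 (trimmed mean) and 0.40 (length-matched); androgen-repressed genes at 0.46 (5 FPKM), 0.23 (1 FPKM in both) and 0.13 (mean); immediate early genes at 0.045 (1 FPKM in both); p53 targets at 0.27 (mean); the unfolded protein list at 0.055 (unmatched, and length-matched); and ribosomal proteins at -0.42 (length-matched). Fewer members enter under the stricter filters, and 1 FPKM in both libraries removes genes near 0 in 1 library, so a call lost there does not show a weak list; otherwise the cause was not tested. Scaling to the same sum moved the median of all genes by 0.11 and gave 864 higher and 539 lower. Depth is unknown, so how far low values vary by counting is open.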

Other observations

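The macrophage RNA test, the test of overlapping genes, its count by pairs (after a first count by genes, 14 of 126) and the count of families that stayed apart when matched on length were chosen only after the result was seen, and the other length-matched tests after the length trend was seen but before they were run. A search of 138 gene families by symbol set 17 apart in the higher direction and 14 in the lower direction, where 6.90 would be by chance. Matched also on transcript length, 13 of the 17 and 8 of the 14 stood apart in the same direction, and the COX, NDUFB and ZNF families were among those that did not (the check is void for the GAGE family, where under 80% of members had a length). All 17 measured HLA genes were at least 2-fold higher in the oe library (median log2 ratio 2.90), including the class II genes HLA-DPA1, at 0.0932 and 38.1 FPKM in the nc and oe libraries, and HLA-DMA, at 3.41 and 32.0 FPKM. CIITA, the master regulator of class II transcription, stood at 0.0106 and 6.49 FPKM, and IFNGR1, a chain of the interferon gamma receptor, at 10.9 and 86.4 FPKM. The complement genes C3, at 0.0121 and 9.16 FPKM, C1R, at 1.21 and 17.7 FPKM, and C1S, at 0.133 and 15.7 FPKM, were higher too. Single genes named in this part were chosen after their values were seen. C3, C1R and C1S each overlap another listed gene on the same strand.

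The 10 measured caspase genes had a median log2 ratio of 0.75, with CASP4, an inflammatory caspase, at 2.57 and 13.7 FPKM and CASP8 at 7.62 and 23.8 FPKM. The 11 TNF receptor family genes had a median of 0.72, with TNFRSF21 at 5.01 and 49.1 FPKM. The 10 MCM genes, mostly subunits of the replicative helicase, had a median of -1.64, and 8 were at least 2-fold lower. The 49 large-subunit mitochondrial ribosomal proteins had a median of -0.58.

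The MHC class II genes were weighed against RNA from macrophages in the culture. Both treatment labels carry the word cocultured, which leaves open whether macrophages were present with the LNCaP cells. The 7 macrophage markers outside MHC class II in the table exceeded their nc level by a median of 5.83 FPKM, 2.32% of the 251 FPKM by which CD74 did, which argues against macrophage RNA as the whole source. The bound used for this test, 10%, was set after the result was seen and without a macrophage library to scale it. LYZ, abundant in macrophages, stood at 0.0382 and 0.603 FPKM and VIM at 4.65 and 6.48 FPKM, but S100A9 exceeded its nc level by as much as CD74 did (107%). The length trend is too small to account for the pattern. Its group medians ran from -0.40 to 0.24, against log2 ratios of 8.48 for HLA-DRA, 7.85 for CD74 and 6.75 for HLA-DRB1. The HLA family lay at percentile 100 among lists matched on expression and transcript length. That percentile adds little, since the family had the highest median of all families in these data and also holds class I genes. A response of the LNCaP cells to the CM, the difference that the labels name, stays open and was not tested.

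Long transcripts were higher and short ones lower in the oe library, with a Spearman rho of 0.32 between log2 ratio and length across 11010 genes, which are not independent replicates. GC content also went with the log2 ratio (rho -0.21). The median was 0.22 in the 1101 genes of lowest GC content and -0.22 in the 1101 of highest. Matched on length in coarse groups, the cell cycle list lay at percentile 0, androgen-induced genes at 0 and oxidative phosphorylation at 0. The cell cycle and androgen-induced lists had median lengths of 3201 and 3929.5 nt. Groups of genes with median lengths of 3010 to 4229 nt had median log2 ratios of 0.005 to 0.11. The trend therefore does not account for the lower cell cycle and androgen-induced lists. The oxidative phosphorylation genes were short (median 1256 nt), and their median of -0.58 lay below the -0.40 of the shortest transcripts. The matching was coarse and the COX and NDUFB families lost their call under it, so how far the trend lowers this list is open. The ribosomal proteins lay at percentile 8.33, so the trend may account for their lower median. The source of the trend, RNA integrity or library preparation against a response of the cells, cannot be told apart, because each group had 1 library. No biological explanation of the trend was tested.

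Some overlapping genes differed in opposite directions, such as ZC3H11A, at 0.275 and 12.8 FPKM in the nc and oe libraries, and ZBED6, at 9.35 and 0.685 FPKM, whose summed values gave a log2 ratio of 0.45. Of 134 overlapping pairs with a gene past 2-fold, 7 (5.22%, 95% Wilson interval 2.55 to 10.4) had both genes past 2-fold in opposite directions, against 4 of 124 pairs of these genes with their nearest neighbour that does not overlap (3.23%, 1.26 to 8.001). Reads assigned differently between overlapping gene models and separate differences of the genes cannot be told apart, because the pairs are few and the intervals overlap. Without any overlapping gene 651 genes were higher and 591 lower. No biological explanation was tested for these pairs.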
